A study of Mus musculus with 8 samples.

How the data were processed

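RNA of 8 libraries of the mouse mammary tumour line MCa-P1362 was measured, 2 libraries for each of 4 groups: EpCAM+ and EpCAM- sorted cells, each of coculture and monoculture. Per the labels, total RNA was sequenced as 150 bp read pairs on an Illumina HiSeq. The processing notes name FastQC, cutadapt, HISAT2, SAMtools, HTSeq and edgeR without versions, and the mouse build mm10. The deposited values are FPKM per gene, in a file per library, as the authors computed them. The tool that wrote them, the annotation and the handling of reads shared between copies of a gene are not given in the sources used here. Whether they were scaled between libraries is not given either; their sums differ. Counts of reads could not be recovered from them, so the depth per library is unknown and no counting interval or limit of detection is given.

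Of the gene names in the files, 6547 were at 0 in all libraries, and 23334 matched a single gene of the GENCODE mouse annotation, which gave Ensembl identifiers, positions and transcript lengths. No mitochondrially encoded gene is in the files, so that share, a usual measure of RNA quality, was not available. Genes at 1 FPKM or more in at least 2 of the 8 libraries were tested (12012). The spread between the 2 libraries of a group was split into a counting term and an excess coefficient of variation, and the relative depths came from the ratio between libraries at which the values of low genes pile up.

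Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, as cell means of the 4 groups over all 8 libraries with 4 residual degrees of freedom (lmFit, contrasts.fit, eBayes with trend). An exact test of 2 against 2 libraries cannot go below p = 0.333, which is why the spread was pooled over the groups. The comparisons were EpCAM+ against EpCAM- in each culture, monoculture against coculture in each fraction, and the interaction, in which the change from coculture to monoculture in EpCAM- is taken from that in EpCAM+. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The moderated test was checked on simulated data with the spread of these libraries, where 88% to 98% of genes changed by 0.50 on the log2 scale were found and between 3.39% and 8.11% of the calls were false. Of genes changed by 0.25, 34% to 56% were found. Only 50 of the 12012 genes were changed at each size, far fewer than were called in the data, so these rates need not hold for the data. Because most genes passed with so small a spread, counts of genes changed by at least 2-fold are given beside the planned counts, a choice made after the data were seen. Other tables were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures with matplotlib 3.10.9.

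Fixed before the data were examined were the groups, tests, gene lists, the alternatives except those named below as added, and the rule for the genes to name. The rule takes the 8 highest and 8 lowest log2 fold changes among genes called, with a mean of at least 5 FPKM in the higher group and no overlap between libraries, in each comparison of groups. For the interaction it takes 4 of each. It adds 22 key genes whatever their values, and up to 4 called members of each list, those with the largest changes. Some genes that the rule takes are not described here, and the numbers of named genes leave them out. Genes named only as Gm followed by a digit or ending in Rik, pseudogenes and genes without a symbol were left out of the ranking. Of 616 genes in 30 lists, 602 were in the files.

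Lists of 5 or more tested genes (23 lists) were tested with camera, a competitive test against the other genes, with a correlation between genes of 0.01. It was repeated with the correlation estimated from the data, and with fry, which tests whether a list's genes move, on balance, in a direction. P-values were adjusted over the 23 lists within a comparison. The lists cover hormone and ERBB receptors, epithelial identity, luminal and basal mammary genes, EMT, collagen and matrix, mesenchymal stem cells, breast cancer stem cells, fibroblasts and pericytes, adipogenic, bone and cartilage lineage, G1/S and G2/M, immediate early and heat shock genes, interferon response, MHC class I presentation, cytokines, hypoxia, cholesterol synthesis, TGF-beta and YAP targets, Wnt and Notch, p53 targets, the unfolded protein response and ribosomal proteins. Lists of leukocyte, endothelial, adipocyte, erythroid, muscle and neural genes, with fewer tested genes, were read as values. The list of mitochondrially encoded genes had no member in the files and gave no value.

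Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, scaling to a constant sum, by the median of ratios and by quantiles, ribosomal protein genes left out, eBayes without trend or with robust fitting, a replicate block, a fit of only the 4 libraries compared, and each library left out in turn. Added after the data were seen were limma's treat against a 1.5-fold change and the subtraction of a share of the other sort fraction. For the latter, 44 genes specific to EpCAM- were taken as those at 50 FPKM or more in both EpCAM- groups and at no more than 0.5% of that level in monoculture EpCAM+. The 39 genes specific to EpCAM+ were taken in the mirrored way. Their median ratio in a group, times the level in the other fraction, was subtracted, and values below 0 were set to 0. Genes of the lists tested are among them, so the subtraction was repeated, after the results were seen, with the medians of the 18 and 15 of them that are in no list and not named in the text. Also added was the summary by chromosome, over 9167 genes of at least 5 FPKM in some group, in windows of about 40 genes. It was repeated after adjustment for GC content, transcript length and mean level in 10 bins each. All 8 libraries and all columns of the files were used.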

Results

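Gene expression was measured by paired-end RNA sequencing of total RNA in 8 libraries of MCa-P1362, a mouse mammary adenocarcinoma cell line raised from a tumour that arose spontaneously in a Balb/c female. The cells had been sorted by flow cytometry on EpCAM, an adhesion protein of the epithelial cell surface. The labels name 4 groups of 2 libraries: EpCAM+ and EpCAM- cells of coculture, and EpCAM+ and EpCAM- cells of monoculture. The protocol states that sorted cells were frozen either straight after the sort or after growth and a passage, and it does not say which of these the words coculture and monoculture stand for. The files hold FPKM, fragments per length of transcript and per depth of library, and 12012 genes reached 1 FPKM in at least 2 libraries and were tested. FPKM summed to between 387489 and 414612 per library, and between 10634 and 11119 genes reached 1 FPKM. The depth in reads is unknown, because the files give FPKM; the low values gave depths of 0.912 to 1.16 relative to monoculture EpCAM+ replicate 1. The labels do not say whether the 2 libraries of a group come from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. That spread was small: beyond a counting term, the coefficient of variation between the 2 libraries of a group was between 0.945% and 2.44%. Across genes, log2 values correlated at r = 0.998 within every group and at r = 0.722 to 0.986 between groups. The main axis of a principal component analysis took 90.8% of the variance and parted EpCAM+ from EpCAM-. The next took 5.71% and 2.68%, and parted the cultures within EpCAM- and within EpCAM+. Levels below are means ± SD over the 2 libraries of a group (n = 2), in FPKM, and changes are log2 fold changes of FPKM + 1, which understate the change of low genes.

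The comparison of EpCAM+ with EpCAM- cells of coculture asks what separates the sorted fractions of the line, whose title names hormone receptors, HER2 and cancer and mesenchymal stem cells. EpCAM+ cells carried the epithelial keratins and junction genes, and EpCAM- cells most of the fibrillar collagen and matrix genes. Epcam itself (chromosome 17, 87635979 to 87651129) stood at 201 ± 1.53 in EpCAM+ and 0.35 ± 0.0128 in EpCAM-. Krt8 and Krt18, the paired keratins of simple epithelium, stood at 3329 ± 35.8 and 2549.6 ± 28.3 in EpCAM+ against 9.63 ± 0.969 and 8.78 ± 0.291 in EpCAM-. Col1a1 (chromosome 11, 94936224 to 94953042), a chain of type I collagen, stood at 72.1 ± 0.468 in EpCAM+ and 4193 ± 42.8 in EpCAM-, a log2 fold change of -5.84 (SE 0.018, adjusted p = 4.71e-13, limma).

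The 8 genes furthest above EpCAM- were Krt8 (8.29), Hp (8.24), Krt16 (8.16), Krt18 (8.03), Cdh1 (8.00), Clu (7.96), Krt19 (7.80) and Spint2 (7.79), with adjusted p from 9.61e-13 to 1.58e-10. They include the adhesion molecule E-cadherin (Cdh1), the acute phase protein haptoglobin (Hp) and the chaperone clusterin (Clu). The 8 furthest below were Col3a1 (-5.87), Col1a2 (-5.87), Col1a1 (-5.84), Acta2 (-5.80), Bgn (-5.79), Col5a2 (-5.77), Col6a3 (-5.73) and Serpinf1 (-5.68), with adjusted p from 4.71e-13 to 1.56e-11. Acta2 encodes smooth muscle actin and Bgn the matrix proteoglycan biglycan. These 8 values lie close together, between -5.87 and -5.68, and follow the share of EpCAM- levels in EpCAM+ described below. With that share subtracted, Col1a1, Col1a2, Col3a1, Col5a2, Acta2, Bgn and Col6a3 were at 0 in both coculture EpCAM+ libraries, and Serpinf1 in 1. These log2 fold changes and their order thus depend on that share. All 34 tested genes of the epithelial identity list were higher in EpCAM+ (median 5.07, camera adjusted p = 3.91e-10). Of the EMT and mesenchymal identity list, 22 of 23 genes were lower and 1 was higher (median -3.96, adjusted p = 7.18e-13), among them Fbn1 (-5.45), Tagln (-5.33) and Prrx1 (-5.06). Vim, the mesenchymal intermediate filament, was 910.5 ± 4.79 in EpCAM+ and 3263 ± 1.31 in EpCAM-, so it was expressed in both. Of the fibrillar collagen and matrix list, 24 of 27 were lower and 3 higher (median -5.31, adjusted p = 6.00e-13), the latter Col6a2 (3.71), Col6a1 (2.61) and Tnc (2.26), named after their values were seen, and of the cancer-associated fibroblast and pericyte list 10 of 12 were lower (adjusted p = 2.09e-05). TGF-beta and YAP targets were lower at 17 and higher at 5 of 23 genes (adjusted p = 2.53e-05), with Ankrd1 at 2.55 among the higher. These 5 calls held with an estimated correlation, at adjusted p = 0.0289 for the epithelial, EMT and collagen lists and 0.0375 for the other 2.

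Among receptors, Erbb2 (HER2, chromosome 11, 98412470 to 98437716) was 15.4 ± 0.494 in EpCAM+ and 8.58 ± 0.197 in EpCAM- (log2 fold change 0.78, SE 0.037, adjusted p = 2.14e-07). Its partner Erbb3 was 12.3 ± 0.236 against 0.0176 ± 0.0145, and Egfr 26.4 ± 0.0189 against 18.1 ± 0.27 (0.52). Esr1 and Pgr fell below the limit for testing. In coculture, the oestrogen receptor gene Esr1 read 0.0597 ± 0.0137 in EpCAM+ and 0.294 ± 0.033 in EpCAM- and the progesterone receptor gene Pgr 0.747 ± 0.0234 and 0.00437 ± 7.57e-05. The prolactin receptor Prlr (5.67) and the EGFR ligand Areg (5.80) were higher in EpCAM+. The hormone and ERBB receptor list as a whole had 8 of 9 tested genes higher (adjusted p = 0.04, and adjusted p = 0.296 with an estimated correlation). The luminal mammary list had 13 of 16 higher and 3 lower (adjusted p = 0.0296, and adjusted p = 0.258 with an estimated correlation). The basal mammary list went both ways, 9 higher and 3 lower of 14 (adjusted p = 0.384), with Krt14 (7.56) and Krt17 (7.07) higher in EpCAM+ and Acta2 lower.

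Stem cell markers split between the fractions. Of the mesenchymal stem cell markers, 11 of 18 were lower in EpCAM+ and 7 higher (median -1.73, adjusted p = 0.00558, and adjusted p = 0.0937 with an estimated correlation). Pdgfrb (-5.44), Cxcl12 (-5.24), Cd248 (-5.21), Thy1 (-5.11), Eng (-4.61), Pdgfra (-3.38) and Ly6a (-1.13) were lower in EpCAM+, while Nt5e, which encodes CD73, was higher at 9.83 ± 0.0415 against 0.324 ± 0.0874. Pdgfrb, Cxcl12, Cd248, Thy1 and Eng are among the genes that give the share of EpCAM- levels described below. Their log2 fold changes depend on it, as do those of Fbn1, Tagln and Prrx1 above. With it subtracted, Pdgfrb was at 0 in both coculture EpCAM+ libraries. Of the breast cancer stem cell markers, 13 of 19 were higher and 6 lower (adjusted p = 0.384). Cd44 was 88.6 ± 0.487 in EpCAM+ and 56.3 ± 0.514 in EpCAM-, Cd24a 437 ± 1.51 and 32.7 ± 0.188, Aldh1a3 29.3 ± 0.221 and 2.24 ± 0.134, and Aldh1a1 0.447 ± 0.121 and 0.0504 ± 0.0273. Sox2 was higher in EpCAM+ (4.85). Mki67, a proliferation marker, was 55.9 ± 1.01 against 38.6 ± 0.357 (0.52). The G2/M list had 24 of 25 genes higher (median 0.68, adjusted p = 9.38e-04, and adjusted p = 0.0937 with an estimated correlation), with Top2a (1.49) and Ube2c (1.35). Hypoxia and glycolysis genes were lower at 17 and higher at 11 of 28 (adjusted p = 0.00425, and adjusted p = 0.258 with an estimated correlation), and unfolded protein response genes lower at 12 and higher at 8 of 22 (adjusted p = 0.0331, and adjusted p = 0.296 with an estimated correlation). Counts of higher and lower genes in a list are over all genes tested. Those adjusted over the list alone were the same for the lists described here unless they are given.

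In the limma test on all 8 libraries, 3188 of the 12012 genes passed an adjusted p of 0.05 with a change of at least 2-fold, 1976 higher and 1212 lower in EpCAM+. That excess of higher genes was not kept by the median of ratios (1482 and 1505) or quantile normalization (1437 and 1556). With no minimum change the count was 10473, 7107 higher and 3366 lower, so that 67.9% were higher. The median of all genes was 0.26, and scaling by the median of ratios moved it by -0.26 and the share of higher calls to 49.9% (50.8% under quantile normalization, which moved it by -0.25). Relative to this median, small differences such as those of Egfr and Mki67 are correspondingly smaller.

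**Figure D1:**
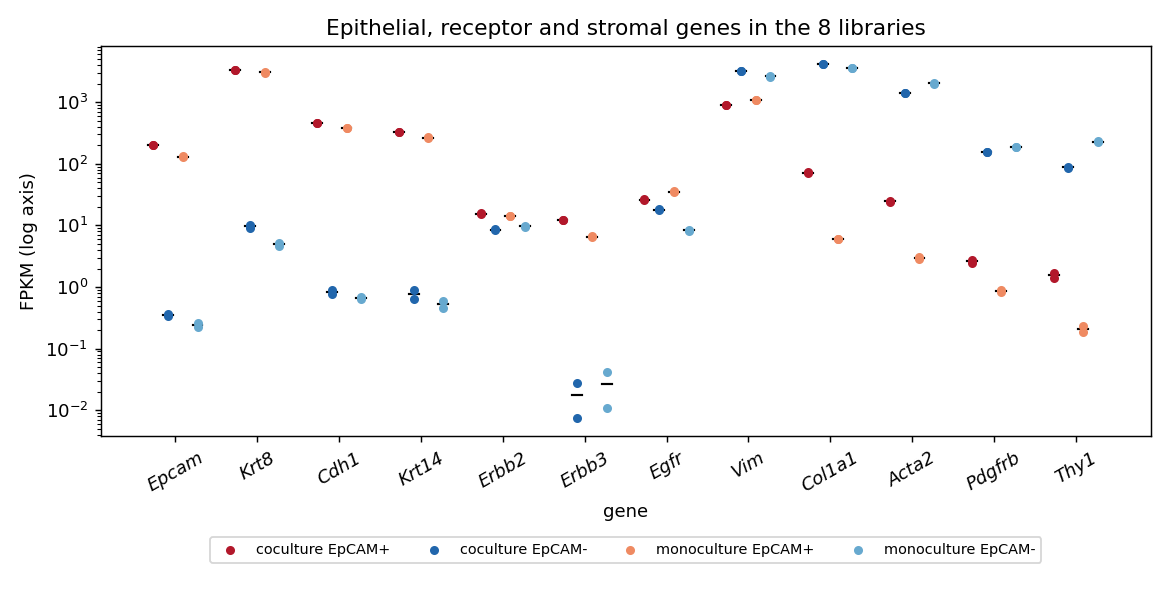
FPKM (log axis) of 12 genes in each of the 8 libraries, with a point per library, a bar at the mean of the 2 libraries and colours for the 4 groups. Epcam lies at 201 and 131 in the EpCAM+ groups and below 1 in both EpCAM- groups, and Col1a1 lies at 72.1 in coculture EpCAM+ and 5.99 in monoculture EpCAM+.

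The same comparison in monoculture asks whether the fractions differ alike there. The epithelial genes were again higher in EpCAM+, and collagens and other stromal genes lower. The median of the collagen list was further below 0 than in coculture (-6.13 and -5.31). With the share of the other fraction subtracted, as described below, 6 of the 27 genes were at 0 in both EpCAM+ libraries of coculture and as many in monoculture, so the cultures could not be ranked by these values. Col1a1 was 5.99 ± 0.0788 in EpCAM+ and 3566 ± 10.4 in EpCAM- (log2 fold change -8.99, SE 0.018, adjusted p = 2.80e-14). Epcam was 131 ± 2.84 against 0.243 ± 0.0244. The 8 highest were Krt8 (9.01), Krt18 (8.86), Clu (8.71), Krt7 (8.28), Krt19 (8.17), Krt16 (7.85), Cdh1 (7.83) and Spint2 (7.70), and the 8 lowest were Bgn (-9.55), Col1a2 (-9.35), Lox (-9.23), Acta2 (-8.999), Col1a1 (-8.99), Serpinf1 (-8.58), Col3a1 (-8.37) and Col5a2 (-8.29), where Lox encodes the collagen crosslinking enzyme lysyl oxidase. Their adjusted p lay between 2.80e-14 and 1.11e-10.

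Epithelial identity genes were higher at 33 of 34 (median 4.55, adjusted p = 2.09e-09). EMT genes were lower at 21 of 23 (median -4.20, adjusted p = 9.33e-10) and collagen and matrix genes at 26 of 27 (median -6.13, adjusted p = 1.84e-14). These 3 held with an estimated correlation, at adjusted p = 0.0352, 0.0429 and 0.0352. Fibroblast and pericyte genes were lower at 10 of 12 (adjusted p = 1.12e-04, and adjusted p = 0.0621 with an estimated correlation), and mesenchymal stem cell markers at 12 of 18 (adjusted p = 0.004, and adjusted p = 0.0915 with an estimated correlation). Among the latter, Ly6a, which encodes the stem cell antigen Sca-1, was 0.467 ± 0.0238 in EpCAM+ and 87.1 ± 3.09 in EpCAM-, Thy1 0.208 ± 0.03 and 229 ± 3.32, and Cxcl12 was lower at -7.78. Eng (-5.87), Pdgfrb (-6.68) and Pdgfra (-4.45) were lower and Nt5e (2.84) higher in EpCAM+. Erbb2 was 14.3 ± 0.0122 against 9.71 ± 0.182 (0.52, adjusted p = 2.59e-06), Erbb3 6.6 ± 0.247 against 0.0263 ± 0.0219, and Egfr 35.5 ± 0.394 against 8.36 ± 0.135. Untested for their low level, Esr1 read 0.00847 ± 0.012 and 0.945 ± 0.00318 and Pgr 0.358 ± 0.00285 and 0.00768 ± 0.0109. Aldh1a1 was 0.0715 ± 0.0594 in EpCAM+ and 3.46 ± 0.302 in EpCAM-, a direction opposite to that in coculture, while Aldh1a3 was 60.1 ± 1.71 and 1.22 ± 0.232. Cd44 (1.42) and Cd24a (4.31) were higher and Vim (-1.26) lower in EpCAM+. The breast cancer stem cell list had 13 higher and 6 lower of 19 (adjusted p = 0.243).

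Interferon response genes were higher in EpCAM+ at 26 of 28 (median 2.00, adjusted p = 3.03e-04, and adjusted p = 0.0915 with an estimated correlation), with Isg15 (4.40), Bst2 (3.48), Usp18 (2.93) and Ifi44 (2.75). In coculture the same list had 18 higher and 6 lower (adjusted p = 0.348). The hormone receptor list had 8 of 9 higher (adjusted p = 0.0266, and adjusted p = 0.242 with an estimated correlation), the luminal list 13 of 16 (adjusted p = 0.0255, and adjusted p = 0.242 with an estimated correlation) and the G2/M list 21 higher and 2 lower of 25 (3 lower adjusted over the list alone; adjusted p = 0.0199, and adjusted p = 0.169 with an estimated correlation). TGF-beta and YAP targets had 14 lower and 8 higher of 23 (adjusted p = 0.0255, and adjusted p = 0.155 with an estimated correlation), unfolded protein response genes 14 lower and 7 higher of 22 (adjusted p = 0.0199, and adjusted p = 0.242 with an estimated correlation) and cholesterol synthesis genes 16 lower and 8 higher of 25 (adjusted p = 0.0369, and adjusted p = 0.169 with an estimated correlation). The hypoxia and glycolysis list, lower at 14 and higher at 10 of 28, was at the threshold (adjusted p = 0.0498, and adjusted p = 0.301 with an estimated correlation). It passed also without monoculture EpCAM+ replicate 2 or monoculture EpCAM- replicate 2. Its adjusted p was 0.0614 without monoculture EpCAM+ replicate 1, 0.0782 without monoculture EpCAM- replicate 1, and 0.0526 to 0.0533 without any of the 4 coculture libraries. Ribosomal protein genes, 20 higher and 2 lower of 27, had a median of 0.22, below the median of all genes of 0.23, and turned negative under the median of ratios (adjusted p = 0.0451, and adjusted p = 0.659 with an estimated correlation). That call was lost without monoculture EpCAM+ replicate 2 (adjusted p = 0.0699) and without coculture EpCAM- replicate 1 or 2 (0.0526 and 0.0527). At 2-fold or more, 3372 genes were called, 1860 higher and 1512 lower, against 1431 and 1831 under the median of ratios and 1533 and 1700 under quantile normalization. With no minimum the count was 10554, 6657 higher and 3897 lower (63.1% higher, 50.3% under the median of ratios, which moved the median of all genes by -0.22; 55.2% under quantile normalization, by -0.15).

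The differences between EpCAM+ and EpCAM- were much alike in the 2 cultures. At 2-fold or more, 1421 genes were higher in both and 1012 lower in both, where independent lists would share 306 and 153, and 9 went in opposite directions. With no minimum change, 5866 were higher in both and 2822 lower in both (3939 and 1092 for independent lists), and 819 were opposite. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.912 and Spearman rho = 0.840.

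By chromosome, the differences between the fractions were uneven, a comparison added after the data were seen. Over genes of at least 5 FPKM in some group, the median log2 fold change of EpCAM+ against EpCAM- in coculture was 0.57 on chromosome 3, 0.55 on chromosome 4 and 0.52 on chromosome 11. On the other chromosomes it lay between 0.08 and 0.31. In monoculture the values were 0.55, 0.55 and 0.54, against 0.07 to 0.36 elsewhere. Erbb2 and Trp53 lie on chromosome 11, where Trp53, which encodes the tumour suppressor p53 and was chosen after its values were seen, was 111 ± 0.629 in EpCAM+ and 61.1 ± 0.556 in EpCAM- of coculture and 131 ± 1.11 and 47.2 ± 0.815 of monoculture. The Erbb2 differences of 0.78 and 0.52 thus stood beside a chromosome median of 0.52 and 0.54.

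**Figure D2:**
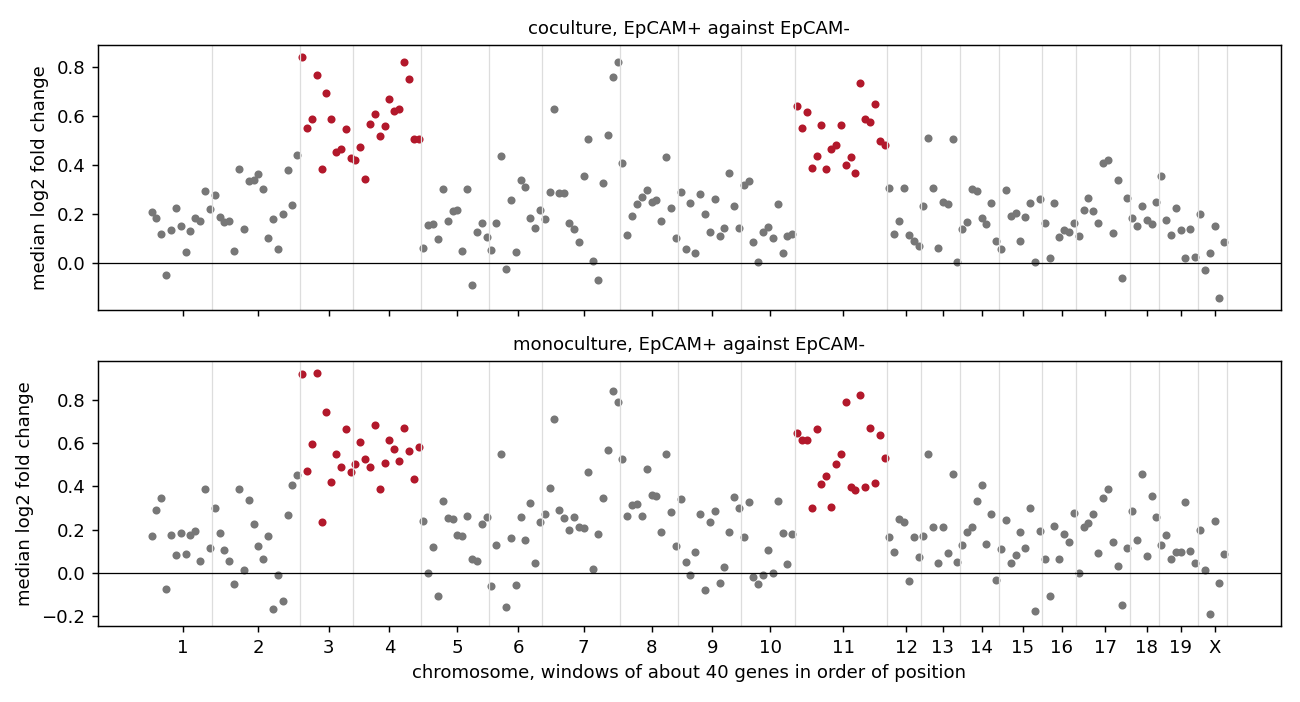
Median log2 fold change of EpCAM+ against EpCAM- (vertical axis) in windows of about 40 genes in order of position (horizontal axis, by chromosome), in coculture above and monoculture below, with chromosomes 3, 4 and 11 in red. The 44 red windows all lie above the median of the windows of the other chromosomes in both cultures.

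The comparison of monoculture with coculture within EpCAM+ cells asks how the epithelial fraction differs between the culture conditions. Interferon-induced, antigen presentation and epithelial genes were lower in monoculture, and a smaller set with Msln and Ptgs2 was higher. Hp was 591 ± 0.0889 in coculture and 83.1 ± 1.53 in monoculture (log2 fold change -2.82, SE 0.117, adjusted p = 1.39e-06). Isg15, a ubiquitin-like protein induced by interferon, was 128 ± 1.13 and 24.7 ± 1.64. Msln, which encodes mesothelin, was 4.3 ± 0.0957 and 18.3 ± 0.506, and Ptgs2, the inducible cyclooxygenase, 28.7 ± 0.317 and 89.2 ± 1.12.

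Interferon response genes fell at 27 of 28 and rose at 0 (median -1.54, adjusted p = 2.11e-16), with Irf7 (-2.55), Isg15 (-2.33), Oasl2 (-2.21) and Rtp4 (-2.05) the furthest. MHC class I presentation genes fell at 14 of 17 (median -0.93, adjusted p = 8.07e-05), with Tap2 (-1.92), Psmb8 (-1.84), H2-Q6 (-1.49) and Psmb9 (-1.44). Epithelial identity genes fell at 28 of 34 and rose at 1 (median -0.36, adjusted p = 9.53e-06), with Ehf (-1.86), Krt23 (-1.77), Elf5 (-1.59) and Ap1m2 (-1.16). Ehf and Elf5 are transcription factors of glandular epithelium. Cholesterol synthesis genes fell at 19 of 25 (20 adjusted over the list alone; median -0.34, adjusted p = 9.16e-05), among them Lss (-0.59), Pmvk (-0.56) and Mvd (-0.52). TGF-beta and YAP targets rose at 13 and fell at 6 of 23 (median 0.14, adjusted p = 9.16e-05), with Ctgf at 1.13 and Inhba at 0.78. These 5 calls held with an estimated correlation, at adjusted p = 0.0296 for the interferon list and 0.0406 for the others. With the share of the other fraction subtracted, as described below, the median was 0.33 for TGF-beta and YAP targets and -0.20 for cholesterol synthesis. Both lists still passed. The p53 targets rose at 11 and fell at 4 of 20 (12 and 5 adjusted over the list alone; adjusted p = 0.00456, and adjusted p = 0.0752 with an estimated correlation).

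Genes of stroma were also lower in monoculture EpCAM+. Of the fibrillar collagen and matrix list, 20 of 27 fell and 4 rose (median -1.37, adjusted p = 5.70e-08, and 0.0406 with an estimated correlation), with Col1a2 (-3.55), Col1a1 (-3.39), Bgn (-3.27) and Col3a1 (-3.16). Of the fibroblast and pericyte list, 9 of 12 fell (10 adjusted over the list alone; adjusted p = 2.30e-04, and 0.0454 with an estimated correlation), with Acta2 at -2.69 and Tagln at -1.44. Serpinf1 (-2.86) and Col5a2 (-2.73) were among the 8 lowest. The levels of such genes followed those of EpCAM- cells. The 44 genes specific to EpCAM- in monoculture stood, in coculture EpCAM+, at a median of 1.80% of their coculture EpCAM- level (quartiles 1.68% and 2.03%). In monoculture EpCAM+ the median was 0.123%. The genes were chosen at no more than 0.5% there, so the choice capped this median and not that of coculture. Once these shares were subtracted, an alternative chosen after the data were seen, the collagen list no longer passed (median 0, adjusted p = 0.117), nor did the fibroblast and pericyte list (adjusted p = 0.385). The subtraction set 6 of the 27 collagen and matrix genes to 0 in both coculture EpCAM+ libraries, Col1a1 among them, so it shows no direction for them. Genes of these lists are among the 44. With shares from the 18 of the 44 that are in no list and not named in the text, 1.77% and 0.109%, the adjusted p of the 2 lists were 0.0966 and 0.342. The interferon list kept a median of -1.55.

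**Figure D3:**
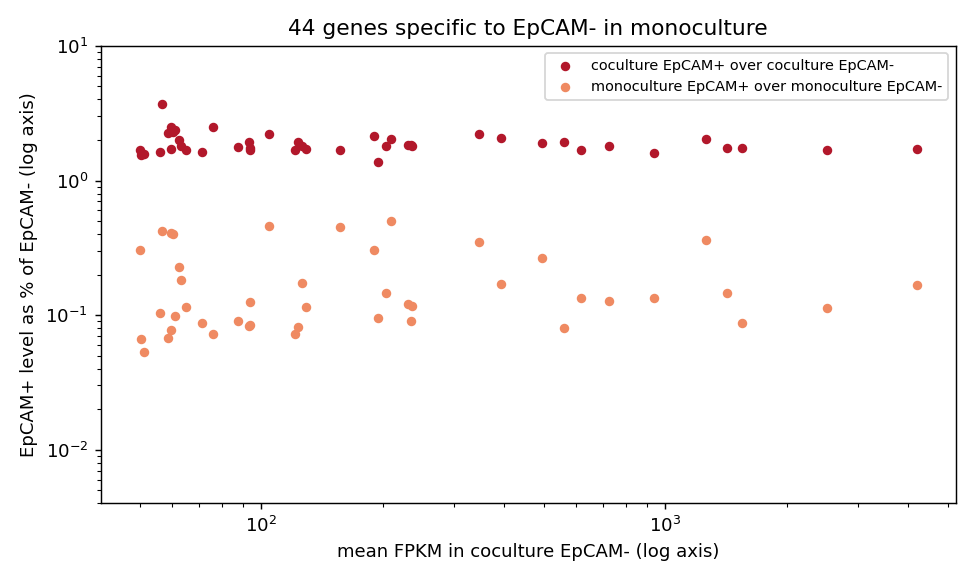
Level in EpCAM+ as a percentage of the level in EpCAM- (log axis) for the 44 genes specific to EpCAM- in monoculture, against their mean FPKM in coculture EpCAM- (log axis), for coculture in dark red and monoculture in orange. The coculture points lie on a nearly flat band around 1.80%, and the monoculture points scatter around 0.123%. The choice of these genes kept the monoculture points at or below 0.5%.

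The 8 highest genes were Msln (1.86), Nppb (1.69), Akap12 (1.61), Ptgs2 (1.60), Fst (1.45), Ddah1 (1.45), Oaz1 (1.39) and Slc12a4 (1.31), with adjusted p from 8.76e-09 to 0.041. Oaz1 varied between replicates (12.4 ± 5.27 and 34.4 ± 15.9), and its call was lost without monoculture EpCAM+ replicate 2 (0.91, adjusted p = 0.217) or coculture EpCAM+ replicate 2 (0.97, adjusted p = 0.209). Without coculture EpCAM- replicate 1 or 2, which change only the shared spread, its adjusted p was 0.0542 and 0.0543. The 8 lowest were Col1a2, Col1a1, Bgn, Col3a1, Col5a2 and Serpinf1, named above, Hp and Zbp1 (-2.77), a sensor of Z-form nucleic acid. Epcam fell (-0.62), as did Cdh1 (-0.30), Krt18 (-0.20), Erbb3 (-0.81), Mki67 (-0.37) and Nt5e (-0.46). Krt8 (-0.13, adjusted p = 0.0949) and Erbb2 (-0.10, adjusted p = 0.0511) did not pass. Aldh1a3 (1.01), Cd44 (0.43), Egfr (0.42) and Vim (0.27) rose, and the breast cancer stem cell list had 6 higher and 7 lower of 19 (adjusted p = 0.137). At 2-fold or more, 233 genes were called, 32 higher and 201 lower in monoculture, and with the shares subtracted 203. The count rose to 562 (73 and 489) with a pseudocount of 0.1, to 355 with scaling to a constant sum and to 364 with ribosomal protein genes left out. With no minimum the count was 6170, 1972 higher and 4198 lower (32.0% higher, 45.7% under the median of ratios and 54.7% under quantile normalization).

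The same comparison within EpCAM- cells asks how the EpCAM- fraction differs between the culture conditions. Interferon-induced genes were far lower in monoculture, and Ptx3, Bmp4 and Mgp were the highest of the named genes there. Usp18 (chromosome 6, 121245906 to 121270917), an interferon-induced protease, was 41.6 ± 0.743 in coculture and 0.335 ± 5.32e-04 in monoculture (log2 fold change -4.996, SE 0.034, adjusted p = 1.56e-10). Bst2 (chromosome 8, 71534255 to 71537456), the antiviral tetherin, was 334 ± 5.63 and 10.3 ± 0.284. Ptx3 (chromosome 3, 66219910 to 66225805), a secreted pattern recognition protein, was 1.98 ± 0.0552 and 130.3 ± 4.32, and Bmp4 (chromosome 14, 46383520 to 46390669), a bone morphogenetic protein, 0.0816 ± 0.0634 and 31.8 ± 0.0656.

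The 8 highest were Ptx3 (5.46), Bmp4 (4.92), Mgp (4.27), Prelp (4.21), Ptn (4.17), Ly6a (4.12), Pcsk6 (3.93) and Igfbp2 (3.92), with adjusted p from 5.31e-10 to 7.32e-08. The 8 lowest were Usp18 (-4.996), Bst2 (-4.89), Irf7 (-4.75), Ifi44 (-4.71), Oasl2 (-4.26), Oas1a (-4.18), Ifi27l2a (-4.05) and Sparcl1 (-4.03), with adjusted p from 4.21e-11 to 4.83e-07. Interferon response genes fell at 26 of 28 (27 adjusted over the list alone) and rose at 1 (median -2.10, adjusted p = 9.37e-16, and 0.032 with an estimated correlation). MHC class I presentation genes fell at 13 of 17 (median -0.55, adjusted p = 7.55e-04, and adjusted p = 0.166 with an estimated correlation), with H2-D1 (-2.22), H2-T23 (-2.01), H2-Q4 (-1.85) and Psmb8 (-1.55).

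**Figure D4:**
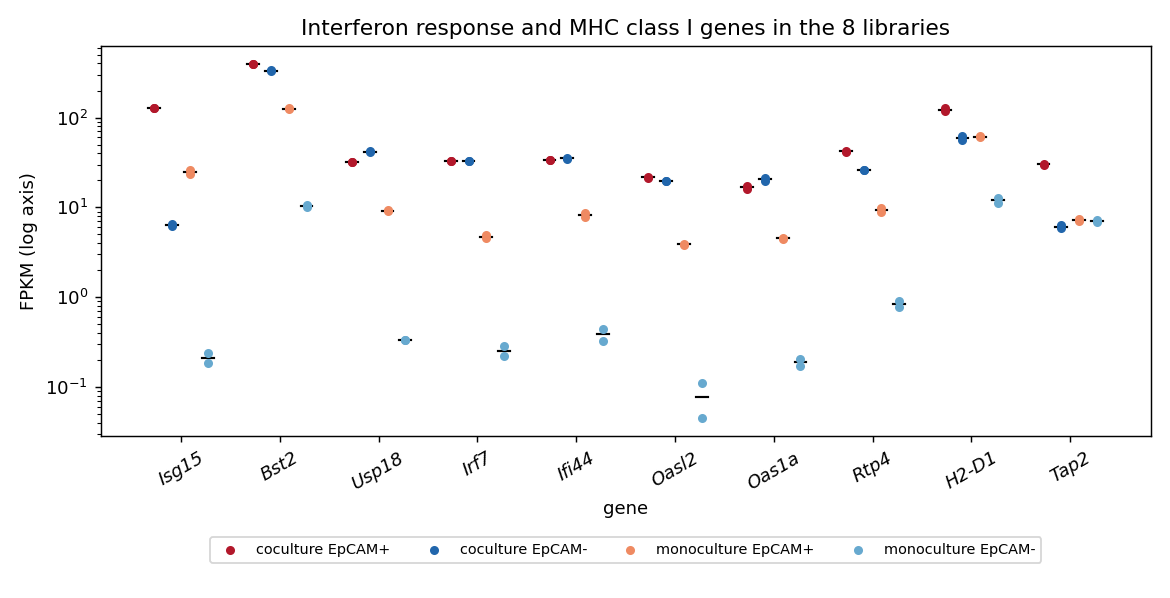
FPKM (log axis) of 10 interferon response and MHC class I genes in each of the 8 libraries, with a point per library, a bar at the mean of the 2 libraries and colours for the 4 groups. In both fractions the coculture points lie above the monoculture points, except for Tap2 in EpCAM-, as for Usp18 at 41.6 and 0.335 in EpCAM- and 32.0 and 9.16 in EpCAM+.

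Collagen and matrix genes rose at 17 and fell at 7 of 27 (8 adjusted over the list alone; median 0.30, adjusted p = 0.0304, and adjusted p = 0.332 with an estimated correlation and 0.105 with the share subtracted), with Col6a2 (3.02), Col6a1 (2.61) and Aspn (2.41). Fibroblast and pericyte genes rose at 9 and fell at 3 of 12 (adjusted p = 0.0304, and adjusted p = 0.189 with an estimated correlation), with S100a4 (2.92) and Cxcl12 (1.80) up and Fap (-2.39), the fibroblast activation protein, down. Mesenchymal stem cell markers went both ways, 10 up and 7 down of 18 (adjusted p = 0.436). Ly6a, Thy1 (1.38), Pdgfra (0.92), Eng (0.33) and Pdgfrb (0.27) rose, while Alcam (-2.30) and Nes (-1.43), which encodes nestin, fell. Aldh1a1 rose from 0.0504 ± 0.0273 to 3.46 ± 0.302. Egfr (-1.03), Cd44 (-0.34), Cd24a (-0.69), Vim (-0.31) and Mki67 (-0.41) fell, and Erbb2 rose by 0.16. The breast cancer stem cell list had 5 up and 10 down of 19 (adjusted p = 0.434).

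Cell cycle lists moved apart: G2/M genes rose at 16 and fell at 3 of 25, and G1/S genes fell at 15 (16 adjusted over the list alone) and rose at 3 of 27. Both had a camera adjusted p = 0.0304, which became adjusted p = 0.227 and 0.189 with an estimated correlation. Cholesterol synthesis genes fell at 15 of 25 (adjusted p = 0.0266, and adjusted p = 0.189 with an estimated correlation). Ribosomal protein genes fell at 19 of 27 by a median of -0.10 (adjusted p = 7.55e-04, and adjusted p = 0.541 with an estimated correlation). Epithelial genes, at low levels here, fell at 11 of 34 (10 adjusted over the list alone; adjusted p = 0.0304, and adjusted p = 0.189 with an estimated correlation and 0.473 with the share subtracted), with Krt18 at 8.78 ± 0.291 and 3.77 ± 0.214. Genes specific to EpCAM+ stood at a median of 0.289% of their EpCAM+ level in coculture EpCAM- (quartiles 0.208% and 0.470%). In monoculture EpCAM- it was 0.20%, where the choice of these genes had capped it at 0.5%. Of these 39 genes, only 43.6% were within 1.5-fold of the coculture median. Their share was thus uneven, and the 0.473 rests on a single share that many of them do not follow. At 2-fold or more, 543 genes were called, 307 higher and 236 lower in monoculture (910 with a pseudocount of 0.1); with no minimum the count was 7527, 3892 higher and 3635 lower.

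The interaction of sort fraction and culture tests whether the culture changes differ between the fractions. At 2-fold or more, 972 genes differed, 292 with the change in EpCAM+ above that in EpCAM- and 680 with it below (1613, or 462 and 1151, with a pseudocount of 0.1), and with no minimum 7826 (3120 and 4706, or 39.9% above and 53.4% under quantile normalization, which moved the median of all genes by 0.11). The 4 highest were Mmp9 (4.31), Mcpt8 (3.70), Usp18 (3.30) and Bst2 (3.23) and the 4 lowest Ptx3 (-5.44), Bmp4 (-5.15), Ptn (-4.84) and Ly6a (-4.78), with adjusted p from 1.75e-09 to 7.28e-06. These 4 lowest were low in EpCAM+ of both cultures. With the share subtracted, their EpCAM+ libraries ran from 0.339 (Bmp4, monoculture) to 1.98 FPKM (Ptn, coculture). Their interaction thus mostly restates the change in EpCAM-. Mmp9, a matrix metalloproteinase, rose in EpCAM+ from 0.35 ± 0.0245 to 2.47 ± 0.131 and fell in EpCAM- from 7.52 ± 0.394 to 0.103 ± 0.00463. The interferon list fell further in EpCAM- (21 genes above and 4 below, 5 adjusted over the list alone; median interaction 0.61, adjusted p = 4.30e-06, and adjusted p = 0.133 with an estimated correlation). Between the culture comparisons of the 2 fractions, 50 genes were at least 2-fold lower in both, where independent lists would share 3.95, 4 were higher in both (0.818) and 16 opposite. With no minimum, 525 were higher in both, 999 lower in both (639 and 1270 for independent lists) and 2710 opposite, and across genes the 2 sets of log2 fold changes had Pearson r = 1.18e-04 and Spearman rho = -0.178.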

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

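The minimum change of 2-fold for the interaction, the tests of an even share and of partial induction, and the tests on the interferon list were chosen after the results were seen; the test on abundant EpCAM- transcripts was written before its result. The change from coculture to monoculture differed between EpCAM+ and EpCAM- by more than 2-fold, in limma's treat test of the interaction, for 64 of the 129 tested genes that the text names; with no minimum, 113 passed. Values are the log2 change in EpCAM+ less that in EpCAM-. Interferon-induced genes above 0, which fell less in EpCAM+, were Usp18 (3.30), Bst2 (3.23), Ifi27l2a (2.84), Ifi44 (2.80), Oas1a (2.49), Irf7 (2.20), Oasl2 (2.06) and Rtp4 (1.84). Others above 0 were Mmp9 (4.31), Mcpt8 (3.70), Sparcl1 (3.09), Ptgs2 (2.47), Inhba (2.34), Alcam (2.22), Fap (2.21), Spp1 (2.18), Ncam1 (1.93), Msln (1.84), Aldh1a3 (1.56), Nes (1.54), Akap12 (1.51), Egfr (1.45), Ddah1 (1.43) and Ctgf (1.28). Genes below 0 that were also more than 10-fold higher, by FPKM + 1, in EpCAM- than in EpCAM+ of coculture were Pdgfrb (-1.23), Eng (-1.26), Fbn1 (-2.07), Col6a3 (-2.08), Cd248 (-2.15), Tagln (-2.30), Thy1 (-2.46), Col3a1 (-2.50), Col5a2 (-2.52), Lpl (-2.54), Cxcl12 (-2.54), Serpinf1 (-2.89), S100a4 (-3.07), Col1a1 (-3.15), Acta2 (-3.20), Col1a2 (-3.48), Lox (-3.66) and Bgn (-3.75). With the share of the other fraction subtracted, 12 of these 18 were at 0 in at least 1 coculture EpCAM+ library, and only 6 stayed below 0 by 2-fold or more, so most of these values depend on that share. The 6 whose sign turned, Col1a1, Col3a1, Pdgfrb, Col5a2, Col1a2 and Acta2, were all at 0 in both, so the turn follows from this floor and shows no direction. Of the 18, 16 are among the genes that give the share; with a share from genes in no list and not named in the text, 6 stayed as well. None of the other genes here turned or fell under 2-fold with the share subtracted. The others below 0 were Csf1 (-1.20), Myh4 (-1.37), Elf5 (-1.61), Krt23 (-1.77), Zbp1 (-1.79), Ehf (-1.83), Tap2 (-2.09), Hp (-2.35), Lcn2 (-2.48), Aldh1a1 (-2.52), Aspn (-2.56), Adm (-3.50), Igfbp2 (-3.92), Col6a1 (-3.99), Pcsk6 (-4.17), Col6a2 (-4.34), Prelp (-4.44), Mgp (-4.51), Ly6a (-4.78), Ptn (-4.84), Bmp4 (-5.15) and Ptx3 (-5.44). Several of these were near 0 in 1 fraction in both cultures, so their interaction mostly restates the change in the other fraction. With the share subtracted, Igfbp2 was at 0 in every EpCAM+ library, and Krt23 and Myh4 in every EpCAM- library.

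Of the lists, 8 differed in the camera test of the interaction. The medians, each with its adjusted p and that with an estimated correlation, were -2.29 (2.23e-05; 0.133) for collagen and matrix, -1.43 (0.00343; 0.133) for fibroblasts and pericytes, -0.42 (0.0265; 0.276) for basal mammary genes, -0.20 (0.0167; 0.262) for G2/M, 0.61 (4.30e-06; 0.133) for the interferon response, 0.24 (0.00544; 0.133) for TGF-beta and YAP targets, 0.15 (0.0445; 0.394) for hypoxia and glycolysis and 0.09 (0.00468; 0.659) for ribosomal proteins. With the share subtracted, the collagen call was lost (adjusted p = 0.949), and the calls of the fibroblast and pericyte list (0.299) and of the basal list (0.128) were lost, while the epithelial list, without a call before (0.151), passed with the change in EpCAM+ below that in EpCAM- (0.00678). The subtraction sets genes of these lists to 0, with 6 of 27 collagen genes in both coculture EpCAM+ libraries and 13 of 34 epithelial genes in both coculture EpCAM- libraries, so it shows what depends on the share and no direction. The hypoxia call was lost without monoculture EpCAM+ replicate 2 (adjusted p = 0.0508) and without coculture EpCAM- replicate 2 (0.0538).

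Stromal transcripts in coculture EpCAM+ lay at an even share of their EpCAM- level: of the 44 genes specific to EpCAM- in monoculture, 97.7% were within 1.5-fold of the median of 1.80%. No such even share was seen the other way, where 43.6% of the 39 genes specific to EpCAM+ were within 1.5-fold of their median in coculture EpCAM-. Of 1460 genes at 50 FPKM or more in coculture EpCAM-, 0% lay below 0.900% in coculture EpCAM+, against 4.77% of 1508 in monoculture. Few genes thus lay below that level even in monoculture EpCAM+, where the median share was 0.123%, so the count is a weak test. The lowest gene in coculture, Col6a3 at 1.38%, was itself among the 44. The even share argued against induction of single stromal genes in epithelial cells, each by its own amount. The upper quartile of the shares was 1.21 times the lower, but it comes from the same 44 shares and is no separate test. Induction of all these genes by a like share would give the same values and was not tested. A candidate explanation is EpCAM- cells or their RNA in the coculture EpCAM+ libraries, which the sort on EpCAM would have to let pass. A like share of EpCAM+ cells in a full mesenchymal state, which was not tested, stays open too.

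The interferon response was lower in monoculture in both fractions. RNA of the other fraction was argued against as its whole cause, since the higher list median of the fractions was still -1.55 after the share was subtracted, and scaling between libraries, since the highest median over the scalings was -1.41. What stays open, untested, is the culture itself and the handling of the sorted cells, which cannot be separated because the labels do not tie freezing after the sort or growth and passage to either culture. A signal from the other cells in coculture may thus be 1 of several candidate explanations.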

How the results depend on the processing

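The tests chosen after the results were seen were limma's treat against a 1.5-fold change, the subtractions of a share and the counts at 2-fold or more under each setting. Of named genes' log2 fold changes, 11173 kept direction and side of the threshold, 123 kept direction but lost the call, 12 gained a call and 37 changed sign. Of list tests, 2207 kept the side of the threshold, 86 lost and 111 gained a call, and 6 that had a call changed direction. For lists without a call in the main test, direction was not compared. Of counts, 254 stayed within 1.5 times their value.

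Against a 1.5-fold change, treat called 4497 genes in the coculture and 4946 in the monoculture comparison of the fractions, 352 and 868 in the culture comparisons of EpCAM+ and EpCAM-, and 1392 in the interaction. A minimum of 2-fold gave 3188, 3372, 233, 543 and 972, and 2433 genes shared between the EpCAM comparisons. Both raise the bar by construction. The counts at 2-fold or more rose with a pseudocount of 0.1, which spreads low values, to 562 and 910 in the culture comparisons of EpCAM+ and EpCAM- and 1613 in the interaction. In that of EpCAM+ they rose to 355 with a constant sum and 364 with ribosomal protein genes left out, which also rescales to a larger sum and so lowers the weight of the pseudocount. List tests with a call in the 4 comparisons of groups went from 42 to 16 with an estimated correlation and 87 with fry, which does not compare with other genes, and those in the interaction from 8 to 0 and 19. With a library left out, each count stayed within 1.5 times its value, such as 4842 to 6235 for EpCAM+ between cultures, and 40 to 45 list tests of the 4 comparisons passed. The replicate block gave 10437, 10512, 5998, 7448 and 7720 genes, and the correlations of replicate differences between groups, -0.0726 to 0.0406 across genes, gave no sign of pairs.

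With the share subtracted, the EpCAM+ culture comparison turned for the fibroblast and pericyte list (adjusted p = 0.385; 6.19e-07 to 0.0454 under the other alternatives) and for the collagen list (0.117; 7.56e-11 to 0.0406), as did the collagen list in the interaction (0.949; 2.49e-07 to 0.133). The subtraction sets Col1a1, Col3a1, Col5a2, Col1a2, Pdgfrb and Acta2 to 0 in both coculture EpCAM+ libraries, and Fbn1 in 1, so the values of these genes below are against a floor and are no measured fold changes. Pdgfra and Ltbp2 were at 0 in no coculture EpCAM+ library, and Krt19 and Perp in no coculture EpCAM- library. The floor does not set the values of these genes, which still depend on the share. In that comparison the log2 fold changes became Col1a1 1.39, Col3a1 0.0871, Col5a2 0.0846, Pdgfra 0.0832, Pdgfrb 0.70, Acta2 0.55, Fbn1 0.0212 and Ltbp2 0.59, and in the interaction Col1a1 1.62, Col3a1 0.75, Pdgfrb 0.44, Col5a2 0.29, Col1a2 0.0721 and Acta2 0.0425. With a share from genes outside the lists, these lists also turned (0.342, 0.0966 and 0.915), and the values became Col1a2 0.12, Col1a1 1.63, Col3a1 0.19, Col5a2 0.18, Pdgfra 0.083, Pdgfrb 0.73, Acta2 0.80, Fbn1 0.032 and Ltbp2 0.56 in that comparison, Krt19 0.49 and Perp 0.13 in that of EpCAM- and Krt8 -0.15, Krt18 -0.22, Pdgfrb 0.46, Col3a1 0.86, Col5a2 0.39, Col1a1 1.87, Acta2 0.29 and Col1a2 0.19 in the interaction. The share of EpCAM+ in coculture EpCAM- was then 0.355% in place of 0.289%, which set Krt8 and Krt18 to 0 in both of its libraries. Under quantile normalization Cd68 turned to -0.0714 in coculture, Ncam1 to -0.0225 in monoculture and Pdgfra to 0.0536 in EpCAM+ between cultures. Under the median of ratios Ncam1 turned to -0.0594 in monoculture. The cause of these 4 was not tested. Calls of small lists at the edge of the threshold also depended on scaling: mesenchymal stem cell markers in coculture were at adjusted p = 0.0785 and G2/M in monoculture at 0.0574 under the median of ratios. Depth in reads is unknown, so no limit of detection can be given for genes near 0, such as Esr1 and Pgr.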

Other observations

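The tests of the chromosomes were chosen after the chromosome medians were seen, while the bounds of those tests were written before their results; the gene lists were fixed before. Single Notch pathway genes were higher in EpCAM+ than in EpCAM-, though the list that holds them had no call: Notch1 stood at 282 and 2.62 FPKM in coculture and 229 and 1.95 in monoculture, and its targets Nrarp and Hey1 at 350.5 and 2.74 and at 226 and 1.95 in coculture. Wnt7b was higher in EpCAM+ (log2 fold change 5.71 in coculture) and Wnt5a lower in monoculture EpCAM- than in coculture EpCAM- (-0.87). The Wnt and Notch list had 13 genes higher and 4 lower of 18 in EpCAM+ of coculture (median 1.68), and its camera adjusted p was 0.161 there, 0.147 in monoculture, 0.137 and 0.962 for the culture comparisons in EpCAM+ and EpCAM-. Cytokine genes split between the fractions. Csf3 (35.2 and 0.122 in coculture EpCAM+ and EpCAM-), Tnf (19 and 0.018) and Cxcl16 (46.2 and 0.607) were higher in EpCAM+, and Ccl7 (2.27 and 126) was higher in EpCAM-. The list of cytokines and chemokines had 13 higher and 6 lower of 19 in coculture EpCAM+ (camera adjusted p = 0.497; 0.243 in monoculture, 0.191 and 0.993 between cultures). Csf1, a macrophage growth factor, rose in EpCAM- from 168 to 411, and Lcn2 fell in EpCAM+ from 12.9 to 1.42.

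The p53 target Perp stood at 362 and 1.75 in coculture EpCAM+ and EpCAM-, and Gdf15 at 11.9 and 42.9. The p53 list had 12 higher and 7 lower of 20 (camera adjusted p = 0.625; 0.225 in monoculture). G1/S genes had 20 higher (21 adjusted over the list alone) and 5 lower of 27 in coculture EpCAM+ (camera adjusted p = 0.345; 0.147 in monoculture), and in the culture comparison of EpCAM+ 3 higher (4 adjusted over the list alone) and 13 lower (0.502). Immediate early and heat shock genes were at adjusted p = 0.464, 0.354, 0.949 and 0.799 in the 4 comparisons of groups, with Fos at 248 and 123 in EpCAM+ of coculture and monoculture. Among adipogenic, bone and cartilage genes, Lpl rose in EpCAM- from 13.1 to 67.6 and Spp1 fell from 83.6 to 13.3, while the list was at adjusted p = 0.589, 0.92, 0.198 and 0.632. Adm, which encodes adrenomedullin and is a member of the hypoxia list, rose in EpCAM- from 8 to 77.2, with the list at adjusted p = 0.104, and 0.0629 in EpCAM+. In EpCAM+ between cultures the hormone receptor list was at 0.949, with 3 higher and 3 lower (6 lower adjusted over the list alone), the EMT list at 0.831, with 7 and 12 (13 lower adjusted over the list alone), the luminal list at 0.502 and the basal list at 0.0534. With the share of the other fraction subtracted, the EMT list passed as higher in monoculture, with 11 higher and 1 lower of 23 (median 0.22, camera adjusted p = 5.08e-05). With the share from genes outside the lists its adjusted p was 4.98e-05. The subtraction set 5 of the 23 to 0 in at least 1 coculture EpCAM+ library, so the EMT result depends on the share. Median, mean and camera differed in sign, without a call, for the adipogenic list in monoculture, for cytokines in both culture comparisons, for breast cancer stem cell markers and the unfolded protein response in the EpCAM- culture comparison and for ribosomal proteins in that of EpCAM+. In the interaction they differed for the hormone receptor, luminal, breast cancer stem cell, immediate early and MHC lists.

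Genes of other cell types were few. Leukocyte genes tested were 3, of which Cd14 stood at 18.2 and 5.34 in coculture EpCAM+ and EpCAM-. Of the 3 endothelial genes, Flt1 stood at 46.5 and 3.7. The adipocyte list had only Fabp4 (0 and 2.4) and the erythroid list 0 tested genes. Of 4 muscle genes, the highest in EpCAM+ were Myh4 (3.16 in coculture, 0.604 in monoculture), Ckm (2.11 and 1.29) and Tnni2 (2.02 and 1.85). Of 3 neural genes, Ncam1 stood at 5.71 and 21.8 in coculture. Gapdh lay at 51.7 in coculture EpCAM+, Rpl26 at 0.609 and Rpl21 at 1.48, beside 1779 for Pkm. These genes have near-identical copies, so their FPKM is uncertain while the handling of shared reads is not given. Ifnb1 read 0.0813 in coculture EpCAM+ and 0 in the other groups.

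On chromosomes 3, 4 and 11, 1789 genes had a median log2 fold change of EpCAM+ against EpCAM- 0.35 above that of the other chromosomes in coculture and 0.36 in monoculture. A bias by GC content, gene length or level was argued against, since 0.33 was left after adjustment for them in the culture with the lower value. The shift ran along these chromosomes, as 100% of the 44 windows lay above the median window of the other chromosomes. That is no independent test of a few clusters with large changes, which could hardly raise the medians by which these chromosomes were picked. Between cultures the excess was 0.0011 in EpCAM+ and 0.003 in EpCAM-. The excess at the 25th percentile was at least 1.04 times that at the median, so the whole distribution was shifted, and a candidate explanation is a difference in the number of copies of these chromosomes between the sort fractions. DNA was not measured, a chromosome-wide difference in regulation was not tested, and distal chromosome 7 also held windows above most others.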
